A study of Sus scrofa with 2 samples.

How the data were processed

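In situ Hi-C, which ligates and sequences pairs of DNA fragments that lie close together in the nucleus, was run on spleen tissue of pig (Sus scrofa) in 2 biological replicates. Per the labels' protocols, formaldehyde-fixed chromatin was cut with DpnII, filled in with biotin and ligated, and the captured fragments were sequenced as paired ends. The analysis started from 2 tables of the whole series, a list of topologically associating domains (TADs, stretches of chromatin that contact themselves more than their surroundings) and a list of chromatin loops (pairs of loci with more contacts than their surroundings). HiC-Pro 3.1.0 is named in the submitters' processing notes. The TAD table is a plain list of starts and ends, all multiples of 10 kb, and its caller and settings are not given in the sources used here. The loop table was written by juicer_tools 1.9.9, per the file headers, with the columns of its HiCCUPS pixel output, and every anchor was 25 kb wide. For each loop the authors' table gives the observed contact count in the pixel, not normalized. The deposited table also holds the expected signal, computed from the donut of pixels around the loop in the unit of the observed contacts. It also gives 4 FDR values per loop, that is q-values against the donut, lower-left, horizontal and vertical neighbourhoods, per the file headers, and the largest value listed was 0.0999. Both tables cover the series and not a replicate, and whether the replicates were pooled before calling is not given in the sources used here. No value per replicate could therefore be computed, no replicate could be left out, and the errors below describe the spread between chromosomes. The sequencing depth of the replicates is unknown here, so the contacts per loop, from 10 to 1004, are the only measure of precision.

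Genes were taken from a RefSeq table of the assembly Sscrofa11.1. No file header names the build. The unplaced scaffold names in the deposited tables are those of Sscrofa11.1 (from general knowledge of that assembly), the autosomal features ended near the last annotated gene of each chromosome, and the density of gene ends peaked at zero offset from anchors and boundaries. Coordinates are those of the deposited tables, counted from 1. The gene table has no strand, so the transcription start sites (TSS) of the fixed design could not be told from the 3′ ends. Each gene's 2 annotated ends were used in their place, and "gene end" below means either of them. The table held 30371 genes, of which 28210 lay on the 20 placed chromosomes and 19550 of those were protein-coding. The 21 gene lists and the rule for naming genes were fixed before the data were examined. Of 757 list entries, 720 matched a protein-coding gene by symbol or by a synonym that a single gene held.

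Features were counted on chromosomes 1 to 18, X and Y in bins of 5 kb. A boundary was each distinct TAD edge, widened by 20 kb on each side, and an anchor was each distinct 25 kb loop end. Counts were compared with circular shifts, in which all features of a chromosome move together by a random offset, in 100000 draws, as a two-sided permutation test. The smallest p these draws can give is 2e-05. Ratios of observed to shifted values have 95% bootstrap intervals over chromosomes (10000 resamples). Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over the 21 lists, and shares have 95% Wilson intervals. These tests and intervals take genes as independent, although neighbouring genes can share an anchor or a boundary. TAD size and gene-end density were compared by Spearman's rho with 100000 permutations. The threshold was 0.05. The genes named were the 20 with the most loops at their ends, ties by longer summed span, and up to 4 genes of each list at anchors. The rule also named the 10 loops with the lowest FDR, ties by longer span, the 5 longest TADs and the 5 boundary windows with the most genes. Some genes that the rule named are not reported here. The FDR of a loop was taken as the largest of its 4 values, a choice made after the table was seen.

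The shift test was tested on simulated data for gene ends at 3814 boundaries. It called 5.5% of 200 simulations with no planted effect and 86% of 50 simulations in which 5% of boundaries were moved onto gene ends. The simulated boundaries were the listed ones moved by a random offset per chromosome, as in the test itself. The rate without an effect therefore checks the computation, and not whether shifts suit real features. A simulated list of 30 genes with 35% of its members at anchors was called, unadjusted, in 64% of 500 simulations. Alternatives fixed beforehand were other window widths, adjoining TAD edges, autosomes alone, the 1701 placed loops with the lowest FDR, all annotated genes, whole anchors inside a TAD, loops moved singly, thinning to a gene per 100 kb, backgrounds matched on gene density and a trimmed range of TAD sizes. Gene midpoints, gene spans, windows displaced by 100 to 500 kb, a single pixel per group of touching pixels, loops under 2 Mb and shifted TADs were added after the data were seen. The tests of gene classes other than protein-coding, of loops by their gene content and of loops joining TAD edges were also added then. No genome sequence was used here, so 6 planned results on repeats and CTCF motifs were not analysed. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, networkx 3.6.1 and matplotlib 3.10.9.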

Results

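Chromatin contacts were mapped by in situ Hi-C in the spleen of pigs, in 2 biological replicates of a single group, in a series on how transposable elements relate to genome folding. The data were a list of 1927 TADs and a list of 3410 loops for the whole series. There was no second tissue or condition, so the comparisons were between the folding features and the genes on the same chromosomes. Repeats themselves were not analysed here.

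The TADs, as listed by a caller whose settings are not given, were short and covered a minor part of the genome. Their median length was 260 kb, with quartiles of 200 and 370 kb and a range from 120 to 3390 kb. They covered 27.5% of the 2434.4 Mb of placed chromosomes, and the median gap between consecutive TADs was 360 kb. Of the TADs, 213 overlapped another and 108 lay inside another. The median length per autosome was 256 ± 21.2 kb (SD, n = 18 chromosomes). TAD density was 0.866 ± 0.211 per Mb (SD, n = 18), from 0.442 on chromosome 11 to 1.38 on chromosome 12. Chromosome X had 15 TADs and chromosome Y had 0. The longest TAD, on chromosome 3 from 12070001 to 15460000, spanned 3390 kb and held 3 protein-coding genes, among them AUTS2, a large gene tied to brain development, and GALNT17. The next was on chromosome 17, from 22740001 to 25300000, with MACROD2, FLRT3 and KIF16B. The TAD on chromosome 8 from 122300001 to 124660000 held PDHA2 and UNC5C. That on chromosome 15, from 6190001 to 8520000, held ZEB2, a transcription factor of neural crest and lymphocyte development, with GTDC1 and ARHGAP15. The fifth, on chromosome 2 from 127150001 to 129370000, held ZNF608 alone.

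Loops joined anchors a median of 175 kb apart, with quartiles of 125 and 275 kb and a range from 100 to 9125 kb. Whether the shortest loops, at 100 kb, and the shortest TADs, at 120 kb, mark limits of the calling is not given in the sources used here. The median loop had 108 observed contacts, and the median ratio of observed to expected contacts was 2.02. Per autosome, loop density was 1.50 ± 0.458 per Mb (SD, n = 18), lowest on chromosome 11 (0.733) and highest on chromosome 12 (2.74). Loops were listed as pixels, and 1784 of them (52.3%) touched another listed pixel, so that the 3410 loops formed 2352 groups. Of 5299 distinct anchors, 1194 belonged to 2 or more loops and 48 to 4 or more.

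**Figure D1:**
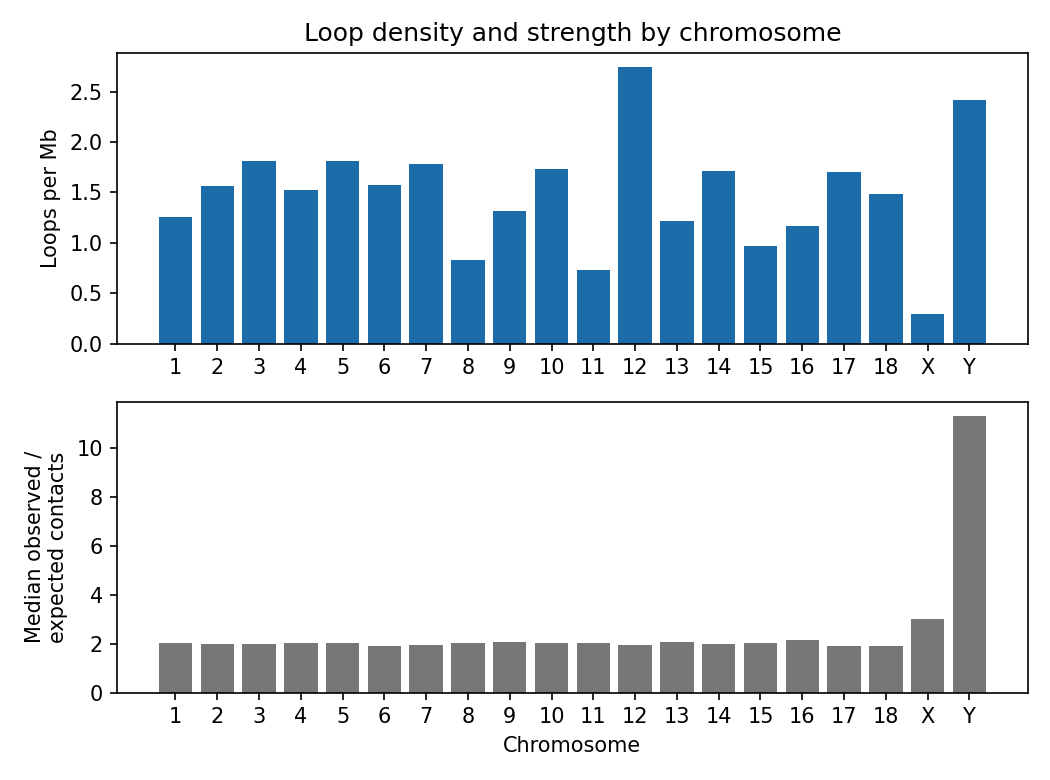
Loops per Mb (upper bars) and the median ratio of observed to expected contacts (lower bars) for each pig chromosome. The 18 autosomes had median ratios from 1.91 to 2.16, against 3.01 on X and 11.3 on Y.

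The sex chromosomes stood apart. Observed contacts were not normalized, and the number of copies of X or Y was not corrected for. Chromosome X had 37 loops with a median of 50 observed contacts, against an autosomal mean of medians of 108 ± 10.9 (SD, n = 18 chromosomes). Chromosome Y had 104 loops with a median span of 712.5 kb, a median of 41.5 observed contacts and a median ratio to expected contacts of 11.3. Of the Y loops, 81 (77.9%) lay at the distal end of the assembled chromosome, between 39550001 and 43025000. Of the 9 anchors with 7 or more loops, 7 were on Y. An FDR of 0 was listed for 26 loops, and the rule took the 10 longest of these. Of the 10, 6 were on Y and joined bins near 41450001 and 41600001 to bins near 42850001 to 43000001, with 169 to 541 observed contacts. None of the 6 had a protein-coding gene end in either anchor, and the last annotated gene of Y ended at 41494726. The other 4 were on autosomes. On chromosome 10, a loop of 4225 kb joined the bin from 15200001 to 15225000, with an end of SCCPDH, to the bin from 19425001 to 19450000, with 113 contacts against 8.76 expected. A second loop nearby on chromosome 10 spanned 3975 kb, with 50 contacts against 1.04 expected, between anchors holding only unnamed loci. On chromosome 17 a loop of 3350 kb had 50 contacts against 0.409 expected. On chromosome 5 a loop of 2950 kb had 101 contacts against 5.91 expected, and its left anchor, from 87275001 to 87300000, held ends of CDK17 and ELK3, an ETS transcription factor.

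**Figure D2:**
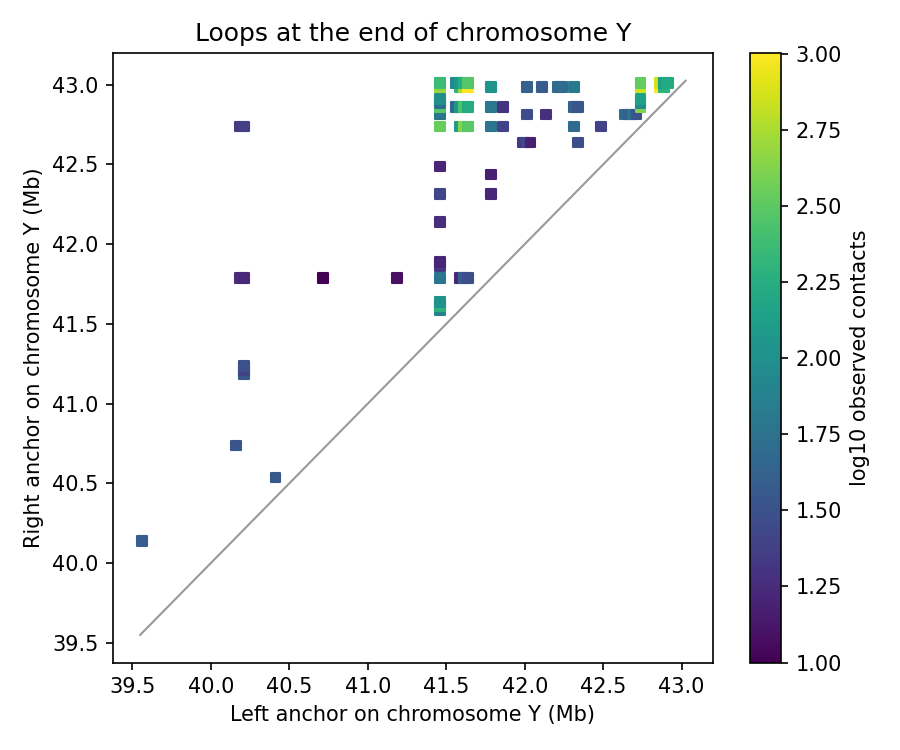
Loops at the distal end of chromosome Y, each square placed by its left anchor (horizontal axis, Mb) and right anchor (vertical axis, Mb) and coloured by the log10 of its observed contacts. The 81 loops formed rows and columns that met at a few shared anchors, with up to 1004 contacts per loop.

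Protein-coding genes were concentrated at loop anchors. An anchor held 0.858 gene ends on average, against 0.439 at shifted positions, a ratio of 1.95 (95% bootstrap interval 1.82 to 2.09), and all 20 chromosomes were higher (permutation p = 2e-05, the smallest these draws can give). Anchors lay in gene-rich neighbourhoods, and against windows displaced by 100 to 500 kb the ratio was 1.31 (1.25 to 1.39). Counted by gene spans, anchors were little richer in genes than shifted positions, with 2.93 bins of 5 kb under a gene per anchor against 2.54, a ratio of 1.16 (1.12 to 1.19). Loops with a gene end at both anchors made up 26.4% of loops against 10.4% at shifted positions, and loops with none at either made up 32.6% against 60.5% (permutation p = 2e-05 for each). Both shares follow in part from the concentration of gene ends at single anchors. Whether loops pair genes with genes beyond that was not tested. On autosomes, the 890 loops with genes at both anchors were shorter than the 996 with genes at neither, with medians of 150 and 200 kb. They had more observed contacts (113 against 101) and a lower ratio to expected contacts (1.95 against 2.05). Each difference had permutation p = 1e-05, the smallest these draws can give. Loops were permuted over all autosomes together, so differences between chromosomes were not separated from gene content. Chromosome 12 had 59 loops with genes at both anchors and 26 with genes at neither, and a median span of 125 kb. Chromosome 1 had 61 and 115, and a median span of 200 kb. Span was not held constant, so the differences in contacts and ratio cannot be told apart from the difference in span. Listed pixels that touch are not independent, and with a single pixel per group of touching pixels (631 and 693 loops) the medians were 150 and 200 kb, 112 and 97 contacts, and ratios of 1.96 and 2.09 (permutation adjusted p of 3e-05 to 9e-05).

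Genes of other classes were also tested, 8 tests in all. Ends of lncRNA genes were 1.75 times as frequent at anchors as at shifted positions (1.63 to 1.89, permutation adjusted p = 8e-05), with all 20 chromosomes higher. Ends of miRNA genes were 1.79 times as frequent (1.13 to 2.36, permutation adjusted p = 0.0303), higher on 10 of 20 chromosomes. This rests on 62 ends, both ends of a gene counted, with 14 on chromosome 12 and 10 on chromosome 5. The miRNA ratio without these chromosomes was not computed. Ends of tRNA genes were 3.01 times as frequent (1.51 to 4.34, permutation adjusted p = 0.00267), higher on 13 of 20 chromosomes. Of 448 tRNA genes, 90 had an end in an anchor, 54 of them on chromosome 7, and without that chromosome the ratio was 1.82 (unadjusted permutation p = 0.121). Pseudogenes missed the threshold at 1.18 times (permutation adjusted p = 0.103).

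**Figure D3:**
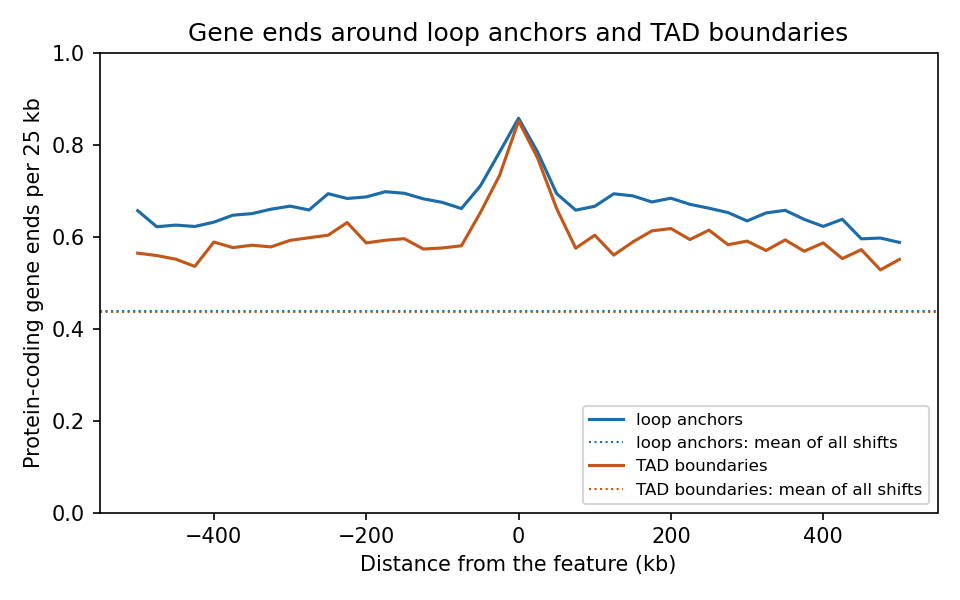
Protein-coding gene ends per 25 kb (vertical axis) by distance in kb from loop anchors (blue) and TAD boundaries (orange), with the mean over all shifts as dotted lines. Both profiles peaked at the feature, at 0.858 for anchors and 0.852 for boundaries, above flanks that were themselves above the mean of 0.439 and 0.436.

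Of the 19550 protein-coding genes, 3382 (17.3%) had an end in an anchor, 2433 of them with 1 loop, 886 with 2 or 3 and 63 with 4 or more. The 20 named genes with the most loops had 4 to 6 each, and 11 of them also lay within 20 kb of a TAD boundary. ABT1 on chromosome 7 had 6 loops of 100 to 625 kb, and its neighbour HMGN4, a nucleosome-binding protein, had 5. SLC16A6, of the monocarboxylate transporter family, had 6 loops of 100 to 175 kb on chromosome 12, with a median of 156 contacts, and its neighbour ARSG, a lysosomal sulfatase, had 5. DUSP4, a phosphatase that acts on MAP kinases, had 5 loops of 275 to 550 kb. The 5 loops of RPL26L1 on chromosome 16 spanned 175 to 225 kb and led to anchors that included an end of DUSP1, another MAP kinase phosphatase. On chromosome 1, ARF6, a small GTPase of membrane traffic, and VCPKMT had 5 loops each, with medians of 175 and 181 contacts. SAMD4A on the same chromosome also had 5. LPCAT4 and NUTM1 shared 5 loops on chromosome 7, with ends of EMC4, EMC7 and AVEN among their partners. PRELP, a leucine-rich matrix protein, had 5 loops on chromosome 9, and FMOD, another such protein, was among its partners. VSIG10L and CLDND2 on chromosome 6 had 4 loops each, all of 2675 to 2725 kb. FBP2, a muscle fructose-bisphosphatase, had 4 loops of 100 to 5250 kb. PLK2, FAM43A, LSG1, GPA33 and MIEF1 had 4 each, and the partners of GPA33 included CD247, the zeta chain of the T cell receptor. Many of these numbers depend on the loops counted. With a single pixel per group of touching pixels, 15 of the 20 genes changed by over 1.5 times. SLC16A6 then had 2 loops and RPL26L1, VSIG10L and CLDND2 had 1 each. In the 1701 loops with the lowest FDR 10 did, and RPL26L1 and PRELP fell from 5 loops to 1.

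The 21 lists, 9 of spleen cell types, 4 of other organs and 8 of other functions, were compared to ask which gene groups meet loop anchors. Neighbouring members of a list can share an anchor, and the tests and intervals do not allow for this. Plasma cell genes had the highest share, with 6 of 13 (46.2%, Wilson interval 23.2 to 70.9%) at an anchor, against 17.3% of other genes. It was followed by megakaryocytes and platelets at 6 of 17 (35.3%), interferon response at 12 of 35 (34.3%, 20.8 to 50.8%), dendritic cells and antigen presentation at 8 of 27 (29.6%), chromatin architecture at 8 of 28 (28.6%) and ribosomal proteins at 20 of 76 (26.3%, 17.7 to 37.2%). Neuronal genes were at anchors in 0 of 35 (up to 9.89%), and skeletal muscle genes in 1 of 29 (3.45%, 0.611 to 17.2%). No list passed after adjustment over the 21 lists, and 5 had an unadjusted p under the threshold by Fisher's exact test. These were neurons (Fisher's exact p = 0.00256, adjusted 0.0538), interferon response (exact p = 0.0129, adjusted 0.106), plasma cells (exact p = 0.0151, adjusted 0.106), ribosomal proteins (exact p = 0.0469, adjusted 0.202) and skeletal muscle (exact p = 0.0482, adjusted 0.202). With anchors extended by 10 kb, plasma cells, interferon response and neurons passed (Fisher's exact adjusted p = 0.0124, 0.0166 and 0.0124), and with a gene per 100 kb, interferon response and neurons did (exact adjusted p = 0.0351 each). Ribosomal proteins passed by gene midpoints (ratio to other genes 2.39 in place of 1.52, exact adjusted p = 0.00824) and neurons by gene spans (exact adjusted p = 0.0108). Against sets matched on gene density, none passed. In the 1701 of 3402 placed loops with the lowest FDR none passed either. Only chromatin architecture, not among the 5 lists above, had an unadjusted p under the threshold there (Fisher's exact p = 0.0419). The 5 lists no longer did, with exact p = 0.115 for plasma cells, 0.136 for interferon response, 0.0727 for neurons, 0.0716 for ribosomal proteins and 0.517 for skeletal muscle. These loops had 2810 distinct anchors against 5285, so fewer genes could lie at an anchor.

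**Figure D4:**
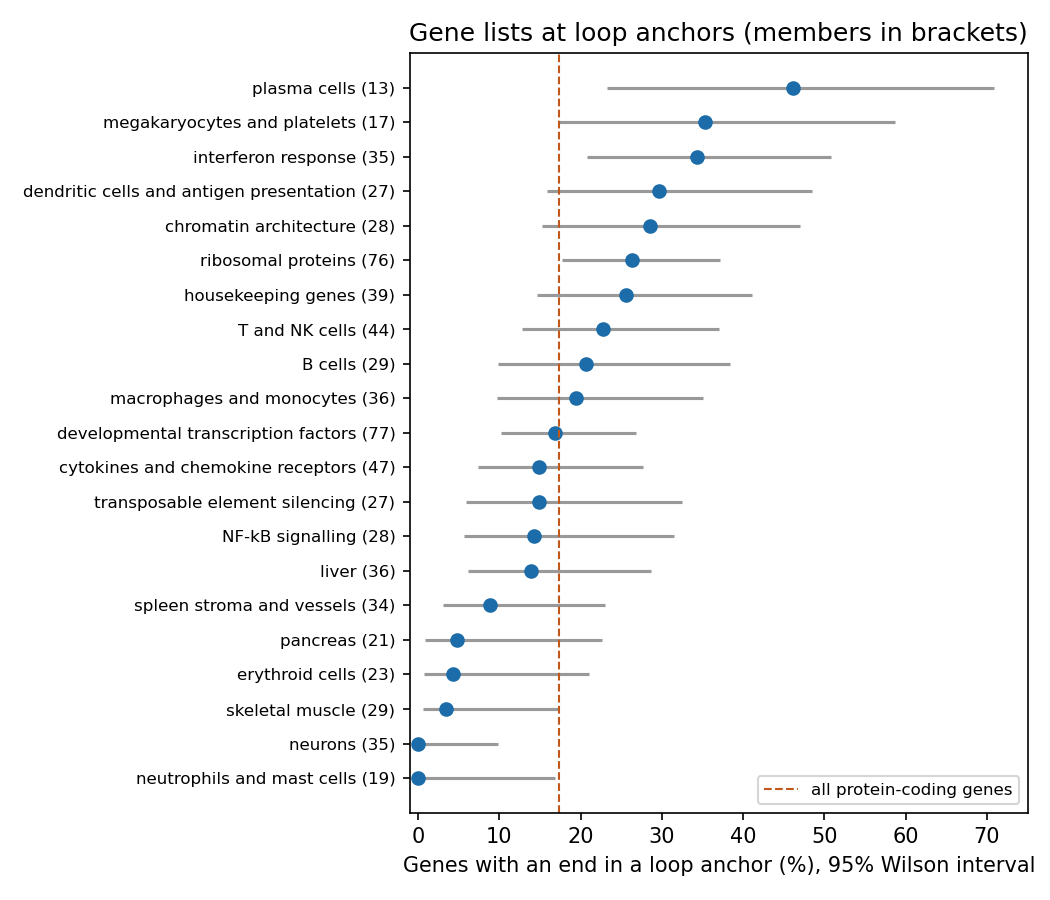
Share of each gene list with a gene end in a loop anchor (horizontal axis, percent; points) with 95% Wilson intervals (lines); the dashed line is the 17.3% of all protein-coding genes. Plasma cells had the highest share (46.2%), and neurons and the list of neutrophils and mast cells were at 0.

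In the plasma cell list, JCHAIN, which joins polymeric immunoglobulin, had 2 loops, as did PRDM1, the repressor that drives plasma cell differentiation. CREB3L2 and ELL2 had 1 each, and 2 further members were at anchors. B cell genes were at anchors in 6 of 29. BCL6, the repressor of the germinal centre, had 3 loops of 250 to 1150 kb and lay at a TAD boundary. TNFRSF13C, the BAFF receptor, had 3 loops with a median of 157 contacts, CD40 and EBF1 had 1 each, and 2 other members were at anchors. T and NK cell genes were at anchors in 10 of 44. CD5 had 3 loops, KLRB1 and NKG7 had 2 each, CCR7 had 1, and 6 other members were at anchors. The loops of NKG7, a protein of cytotoxic granules, spanned 2675 and 2700 kb. They had 36.8 and 47.2 expected contacts, against a median of 5.93 for autosomal loops of 1 to 2 Mb. Among macrophage and monocyte genes (7 of 36), FCER1G, the Fc receptor gamma chain, had 4 loops and the transcription factor CEBPB had 2. MERTK, a receptor for dying cells, had 2, C1QB had 1, and 3 others were at anchors.

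The list of dendritic cells and antigen presentation had 8 of 27 members at anchors. PSMB9, a subunit of the immunoproteasome, had 2 loops, and FLT3, NLRC5 and a CD1 gene had 1 each, with 4 others at anchors. PSMB9 and these 4 others all lay on chromosome 7, so the 8 members were not spread evenly over the genome. Megakaryocyte and platelet genes were at anchors in 6 of 17, with 1 loop each for GATA2, GP9, ITGA2B, ITGB3 and the 2 others. Of 23 erythroid genes, AHSP, the chaperone of alpha globin, was the single member at an anchor. Of 34 stromal and vessel genes 3 were, namely PDGFRA with 2 loops and ENG and LTA with 1. None of 19 neutrophil and mast cell genes was (up to 16.8%). The interferon response genes at anchors were led by IFNGR2 with 3 loops and DHX58 with 2, and DDX58, a sensor of viral RNA, and EIF2AK2, the double-stranded RNA-activated kinase, had 1 each. Cytokine and receptor genes were at anchors in 7 of 47, with 3 loops for CXCL16 and 1 each for CCR7 and CXCL9. NF-kB genes were in 4 of 28, CYLD, MAP3K14, NFKBIA and TRAF6, with 1 loop each.

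Among genes of general function, RPL11 and RPS9 had 3 loops each and RPL3 and RPL31 had 2, with 16 other ribosomal proteins at anchors. Of the RPS9 loops, 2 spanned 2825 kb on chromosome 6, overlapping the loops of NKG7. They had 21 and 47 contacts against 4.07 and 15.4 expected, with FDR of 0.042 and 0.078. Housekeeping genes were at anchors in 10 of 39, with 2 loops each for EMC7 and VPS29 and 1 each for ACTB and EEF1A1. Chromatin architecture genes were at anchors in 8 of 28. CTCF, the insulator protein that marks loop anchors, and SMC3, a cohesin subunit, had 2 loops each, and ESCO1 and LMNB1 had 1. Genes that silence transposable elements were at anchors in 4 of 27, CBX3, CBX5, DAXX and DNMT3A, with 1 loop each (Fisher's exact p = 1). Developmental transcription factors were at anchors in 13 of 77, with 3 loops for HOXC8 and 2 each for EMX2 and FOXF1. HOXC8 shared its 2 adjoining anchors with other HOXC genes of the list. Of genes of other organs, 5 of 36 liver genes were at anchors. APOA2, which shared its anchor with FCER1G, had 4 loops, ASGR1 had 2 and CPS1 had 1. CTRC was the single member of 21 pancreas genes, and MYOD1 the single skeletal muscle gene.

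Loops followed the TADs. Anchors lay within 20 kb of a boundary in 39.6% of cases, against 9.85% at shifted positions, a ratio of 4.02 (3.65 to 4.42). With only the edges of adjoining TADs, 3.53% of anchors lay that close against 0.451%, a ratio of 7.82 (6.45 to 9.56). Both anchor midpoints fell in the same TAD for 53.3% of loops, against 14.9% at shifted positions (ratio 3.59, 3.34 to 3.88). Loops that joined both edges of the same TAD made up 24.7% of loops, 815 in number, against 0.655% at shifted positions (ratio 37.7, 32.5 to 43.5). With only adjoining TADs the share was higher on all 17 chromosomes compared, and the other shares were higher on all 19 chromosomes with TADs. Each had permutation p = 2e-05, the smallest these draws can give. Both lists came from the same Hi-C series and were not independent measurements.

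Protein-coding genes were also concentrated at TAD boundaries. A window of 20 kb on each side of a boundary held 1.32 gene ends against 0.698 at shifted positions, a ratio of 1.89 (1.77 to 2.01), higher on all 19 chromosomes (permutation p = 2e-05, the smallest these draws can give). Against displaced windows the ratio was 1.42 (1.36 to 1.49), and by gene spans against shifted positions it was 1.18 (1.14 to 1.22). Ends of lncRNA genes were 1.44 times as frequent as at shifted positions (1.32 to 1.58, permutation adjusted p = 8e-05), and miRNA, tRNA and pseudogenes missed the threshold (permutation adjusted p = 0.103, 0.737 and 0.447). Of the 5 boundary windows with the most genes, that on chromosome 18 from 45390001 to 45430000 lay in the HOXA cluster of body-axis regulators, with ends of HOXA3, HOXA5, HOXA6, HOXA7, HOXA9, HOXA10 and HOXA11. That on chromosome 12 from 44940001 to 44980000 held SUPT6H, PROCA1, RAB34, RPL23A, TLCD1, NEK8 and TRAF4. That on chromosome 3 from 39960001 to 40000000 held ZNF598, SYNGR3, GFER, NOXO1, TBL3, RPS2 and RNF151. The other 2, on chromosomes 4 and 2, held 9 and 8 genes without names.

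Of all protein-coding genes, 3647 (18.7%) had an end at a boundary, and none of the 21 lists passed after adjustment. By Fisher's exact test 2 lists had an unadjusted p under the threshold. Ribosomal proteins were at boundaries in 23 of 76 (30.3%, Wilson interval 21.1 to 41.3%, exact p = 0.017, adjusted 0.357), and developmental transcription factors in 22 of 77 (28.6%, 19.7 to 39.5%, exact p = 0.0385, adjusted 0.404). Placed by gene midpoints instead of gene ends, both passed (Fisher's exact adjusted p = 7.62e-05 and 0.0155). With a gene per 100 kb, which left 48 developmental factors, 10 of these (20.8%) were at boundaries against 19.8% of other genes, a ratio of 1.051 (Fisher's exact adjusted p = 1). Plasma cell genes, the list with the highest share at anchors, were at boundaries in 2 of 13 (15.4%, 4.33 to 42.2%), and neuronal genes in 4 of 35 (11.4%, 4.54 to 26.0%).

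Shorter TADs were denser in genes. Across 1923 TADs, which are not independent replicates, Spearman's rho of TAD size with gene ends per Mb was -0.41 (permutation p = 1e-05, the smallest these draws can give). Ordered by size into 4 equal classes, TADs with a median of 170 kb held 34.8 gene ends per Mb, those of 220 kb held 25.8, those of 300 kb held 23.5 and those of 670 kb held 10.04. With all TADs of a chromosome shifted together, rho averaged 0.0484 (95% of 1000 shifts between 0.00246 and 0.0929).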

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

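The tests of explanations in this part were chosen after the results were seen. Signals outside the chromosomes compared above came from unplaced scaffolds, which held 8 loops with 60 to 145 observed contacts on 3 scaffolds, and 4 TADs. They were set apart because no comparison used them.

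The loops of chromosome Y were long and concentrated at the distal end of the assembly. Over all loops, Y had fewer observed contacts than autosomes (medians 41.5 and 109) and far fewer expected ones (5.17 and 53.7). At like distance, among loops of 1 to 2 Mb, the medians were 92 on Y (36 loops) and 35 on autosomes (45 loops), but the Y loops formed only 3 sets linked by shared or touching anchors, and between sets the medians were 21 and 34 (permutation p = 0.507). Expected contacts in this range were not lower on Y by loops (medians 6.47 and 5.93), which goes against low expected contacts as the cause, but between sets they were 0.275 and 6.14 (permutation p = 0.437). With 3 sets neither comparison decides, and low expected contacts alone stay open. Sequence present in several copies, or placed wrongly in the assembly, could join a few bins in all combinations: the closed share of joined anchor triples was 0.394 on Y against 0.143 on the highest autosome over all pixels, past a bound of 2 times, and 0.355 against 0.214 with a single pixel per group of touching pixels, short of it. Each of the 2 autosomal shares rests on 1 closed triple. With a single pixel per group, Y had 25 closed triples against 8 on all autosomes together. A true hub of contacts would also close triples, so copied sequence and a hub cannot be told apart from these values. No biological explanation was tested.

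Gene ends at loop anchors and TAD boundaries might reflect only the gene-rich neighbourhoods in which these features lie. For neighbourhoods that reach across the displaced windows, the ratio would be near 1 against windows displaced by 100 to 500 kb. It was 1.31 at anchors (95% bootstrap interval from 1.25) and 1.42 at boundaries (from 1.36). Neighbourhoods that broad were therefore not the whole cause, although the ratios were smaller than the 1.95 and 1.89 against shifts along the whole chromosome. Gene clusters narrower than 100 kb around the features would also give ratios above 1, and were not tested. Whether reads map better near genes was not tested, and no biological explanation was tested.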

How the results depend on the processing

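Gene midpoints, gene spans, displaced windows and a single pixel per group of touching pixels were chosen after seeing the data. The concentration of gene ends at anchors and boundaries, of anchors at boundaries, of loops inside a TAD, and the relation of TAD size to gene density kept their direction and stayed past the threshold under every alternative run. Their weakest ratios were 1.16 at anchors and 1.18 at boundaries, both with gene spans, 3.12 for anchors near boundaries (up to 7.82 with only adjoining TADs), 2.91 for loops inside a TAD and a rho of -0.339. The 1701 loops with the lowest FDR replaced 3402 by construction. GC-matched backgrounds, and every alternative of the 6 results on repeats and CTCF motifs, were not run, since no genome was used. No replicate could be left out, and depth per replicate is unknown here.

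The number of lists past the adjusted threshold at anchors went from 0 to 3 with anchors extended by 10 kb, to 2 with a gene per 100 kb, and to 1 with gene spans (neurons) and 1 with midpoints (ribosomal proteins). In the loops with the lowest FDR it stayed at 0. There 1 list, not among the 5 before, had an unadjusted p under the threshold. Those loops had 2810 distinct anchors against 5285, so a lost threshold does not by itself show a weaker ratio. At boundaries the number of lists past the adjusted threshold went from 0 to 2 with midpoints. The cause was not tested. Lists that crossed a ratio of 1 to other genes, none past the adjusted threshold on either side, follow by setting. At anchors extended by 10 kb, NF-kB genes had 1.31, cytokines 1.04 and liver 1.02. In the loops with the lowest FDR, T and NK cells had 0.971, developmental factors 1.39, housekeeping genes 0.821 and macrophages 0.593. At anchors by midpoints, chromatin architecture had 0.715, cytokines 1.07, developmental factors 1.43 and transposable element silencing 1.11. By spans, macrophages had 0.939. With a single pixel per group, cytokines and transposable element silencing had 1.01 and 1.00. At boundaries with a window of 10 kb, erythroid genes had 1.18, housekeeping 1.16, liver 1.51, macrophages 1.25, neutrophils 1.43, stroma 1.06 and transposable element silencing 0.334. With 50 kb, NF-kB genes had 1.053, macrophages 1.31, megakaryocytes 1.56, neutrophils 1.09 and plasma cells 1.36. By midpoints, dendritic cells had 0.339, macrophages 1.27, neutrophils 1.45, stroma 1.08 and transposable element silencing 0.678. By spans, T and NK cells had 0.946 and megakaryocytes 1.36, and with a gene per 100 kb T and NK cells had 0.862. The cause was not tested for any of them. Of the 20 genes with the most loops, 10 had their number change by over 1.5 times in the loops with the lowest FDR and 15 with a single pixel per group. Both settings drop loops, so these numbers could only stay or fall.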

Other observations

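All tests in this part were chosen after the results were seen. Apart from the loops on Y, 36 autosomal loops spanned at least 2 Mb, in 26 groups of touching pixels. Of these, 11 lay on chromosome 6 between 55775001 and 58775000. The expected contacts of these 11 ran from 1.29 to 47.2, against a median of 5.93 for autosomal loops of 1 to 2 Mb. Genes named here outside the fixed rule were chosen after their values were seen. In this stretch, an anchor with ends of CLDND2, ETFB and VSIG10L met the bin from 55800001 to 55825000 with 138 contacts against 23.7 expected, and an anchor with OSCAR and TARM1, receptors of myeloid cells, met the bin from 58750001 to 58775000 with 56 against 21.4. On chromosome 10 the anchor with SCCPDH also met a bin with ends of TLR5, the flagellin receptor, and SUSD4, at 83 contacts against 5.92 expected. On chromosome 16 the longest loop of the list, 9125 kb, met an anchor with SLC38A9 at 38 contacts against 1.43 expected. Whether sequence was placed wrongly in the assembly was not tested for any autosomal loop. Pairs of neighbouring immune genes shared an anchor, IL4 with IL13 on chromosome 2 and LTA with TNF on chromosome 7.

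In a grouping of the lists made after their shares were seen, the 9 lists of spleen cells together had 47 of 239 genes at anchors (19.7%, Wilson interval 15.1 to 25.2%), and the 4 lists of liver, pancreas, skeletal muscle and neurons had 7 of 121 (5.79%, 2.83 to 11.5%). The share of spleen genes was close to the 17.3% of all protein-coding genes, and lists within each group differed widely. Liver held 5 of the 7 other-organ genes, and without it the share of the other organs was 2.35%. Among the spleen lists, neutrophils and mast cells (0 of 19), erythroid cells (1 of 23) and stroma and vessels (3 of 34) were low too. With lists as units, 37 of the 715 ways to set 4 of these lists against the other 9 gave a difference as large (exact p = 0.0517), and with the share of genes of equal density subtracted 32 did (exact p = 0.0448). The values fall on either side of the threshold, for a grouping made after the shares were seen, so the contrast may be a matter of chance. The subtraction moved the difference only from 13.9 to 14.0 percentage points, although spleen genes had a median of 9 genes within 250 kb and other-organ genes 6. With the 2 groups mixed within 5 classes of gene density, 36.4 spleen genes were expected at anchors against the 47 found. These values argue against local gene density, measured in this way, as the source of the contrast, which may itself be a matter of chance. At TAD boundaries the shares were 17.99% and 10.7%. Expression was not measured here, so whether use of these genes in the spleen plays a part stays an untested hypothesis.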
